A study of Rattus norvegicus with 6 samples.

How the data were processed

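Airway epithelium of 6 male F344/NCrR rats was measured, 3 controls and 3 rats taken 2 days after LPS. Per the labels' protocols, epithelium was laser-captured from frozen sections of 8 µm, 5 large airways were taken per rat, RNA was amplified in 2 rounds, and biotin-labelled cRNA was hybridised. Groups and replicate numbers come from the sample titles, which call the replicates biological.

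Per the file headers, each array's deposited table gives an average difference, a background-subtracted intensity, and a call of present, marginal or absent for each of 8799 probe sets. The average difference is the mean of perfect-match minus mismatch intensity over the probe pairs of a probe set, on a linear scale, and it can be negative. The scaling applied by the authors is not given in the sources used here. The deposited value table of the series holds the same intensity values (largest difference 0). Between 27.1% and 29.8% of the average differences on an array were at or below 0.

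The trimmed means of the arrays, leaving out the lowest and highest 2% of probe sets, ran from 271 to 587.8, which exceeded the 5% tolerance set before the data were examined. The values were therefore turned to log2 and quantile normalised between arrays. Values at or below 0 were first set to the array's lowest positive value, 0.1 or 0.2. Control probe sets were left out, and probe sets called present on at least 3 of the 6 arrays, in either group, were tested.

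Tests used R 4.3.3 and limma 3.58.1, with lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over all probe sets tested and an adjusted p threshold of 0.05. No replicate block was used. Errors of log2 changes are the standard errors of the moderated fit. Of the 8740 probe sets that are not controls, 7006 name 1 gene, 308 several and 1426 none in the platform annotation; 6985 of the single-gene probe sets matched the reference gene table (assembly GRCr8), which was used for current symbols only. A gene with several tested probe sets is represented by the one with the highest mean signal, and no gene had called probe sets in opposite directions. Of the 166 called genes 35 had another tested probe set; for 15 it was called the same way, and for 20, among them Cyp2a3, Cd14, Cp, Pdia3, Acsl1, Gadd45a, Sod1, Nat1 and Tagln, none was called.

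The 29 gene lists, 19 of processes and 10 of markers of other cells, were fixed before the data were examined. Lists with at least 5 measured members (18 process and 3 marker lists) were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted within each kind; camera with an estimated correlation and fry were run beside it. The genes named were the 8 with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap, up to 3 called members of each list, the 2 brightest members of a list with fewer than 2 called, and Muc5ac, Bcl2, Igf1, Scgb1a1 and Foxj1. Other called list members and the surfactant, leukocyte and muscle genes outside that rule were chosen after their values were seen.

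A gene that was absent on every array of its dimmer group, or had a value at or below 0 there, has only a bound. Its fold is then given as at least the brighter group's mean over the dimmer group's, with values raised to a detection level, the 5th percentile of average differences called present on that array. Such a bound takes no account of sampling error. For some genes, Ptgs2, Pla2g2a and Cyp4b1 among them, the 95% interval of the fold without raised values reached below it. This rule, and the ranking of such genes by their bound, were chosen after the data were seen. Of the 241 called probe sets, 9 had a value at or below 0.

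On simulated data built from these arrays (5 simulations, 3011 probe sets), 34.8% of planted log2 changes of 1 and 78% of planted changes of 2 were recovered, with 8.6 false calls on average. Shifted lists of 20 genes were called in 100% and unshifted lists in 4% of 50 draws. Simulated genes varied independently of one another, so these rates do not cover lists whose members are correlated. Alternatives covered normalization, a pseudocount of 16 or 64, the filter, the variance model, array weights, a replicate block, leaving out each array, an unmoderated t statistic, the correlation and the probe set per gene. A floor of 20 or 100 and leaving out probe sets at or below 0 were added after the data were seen. The arrays' Spearman correlations were 0.911 to 0.937 within controls, 0.947 to 0.965 within LPS and 0.855 to 0.899 between groups.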

Results

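Gene expression was measured in airway epithelium of male F344/NCrR rats, an inbred strain, at an age of 8 to 10 weeks. One group of 3 rats had received 1000 µg of lipopolysaccharide (LPS) from Pseudomonas aeruginosa in 0.5 ml of saline 2 days earlier. LPS is an outer-membrane component of Gram-negative bacteria that is sensed through Toll-like receptors. The control group of 3 rats received no instillation, so LPS and the act of instillation differ together between the groups. The labels speak of both an intratracheal and an intranasal route, and the route is left open here. Epithelium of 5 large airways per rat had been collected by laser capture, in which cells are lifted from a tissue section under the microscope, and its RNA was amplified and hybridised to 1 Affymetrix rat array per rat. Each array held 8740 probe sets for rat transcripts. The control arrays had 2748 to 2870 present calls and the LPS arrays 2926 to 3156. The number of arrays limits the precision of every value below.

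The comparison of LPS arrays with control arrays asks which transcripts of the captured tissue differed 2 days after LPS. The lists of antimicrobial and acute-phase genes and of the secretory pathway were shifted upward and the list of club-cell genes downward. The cytokine and NF-kB lists were shifted upward and the xenobiotic list downward at the preset correlation, with adjusted p = 0.207, 0.0844 and 0.0844 with an estimated correlation. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was at least 22.1-fold higher (adjusted p = 0.0069). Such a bound allows for signals below detection and not for sampling error. The 95% interval of the Ptgs2 fold, without raised values, started at 12.8. The sulfotransferase gene Sult1c3 was 19.4-fold higher (log2 change 4.28 ± 0.61 SE, n = 3 per group, adjusted p = 0.0072). The control values of Sult1c3 were 6.29, 9 and 8.32 (log2), so its fold depends on the control arrays used. Cyp4b1, a cytochrome P450 of lung epithelium, was at least 18.3-fold lower (adjusted p = 0.0019). Scgb1a1, which encodes the main secretory protein of club cells, was 4.06-fold lower (log2 change -2.02 ± 0.34 SE, n = 3 per group, adjusted p = 0.012).

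Among 3011 probe sets tested with limma, 241 passed a Benjamini-Hochberg adjusted p of 0.05, of which 156 were higher and 85 lower after LPS. In all 241 the 3 LPS values lay on one side of the 3 control values. Over all tested probe sets that held for 31.1%, against 10% by chance. The probe sets naming a single gene gave 111 higher and 55 lower genes of 2014 tested. Of the 241, 136 were at least 2-fold higher and 61 at least 2-fold lower. The count was 137, 78 and 98 without LPS replicate 1, 2 and 3, 103 with no filter on dim probe sets, of which 59 were among the 241, and 59 with an unmoderated t statistic. It was higher, at 289 and 319, with a pseudocount of 16 and 64, and 328 with array weights. Of 47 called genes followed through the alternatives, 34 lost their call with no filter, Ptgs2, Sult1c3, Scgb1a1 and Cyp2a3 among them, and 37 with the unmoderated t statistic. Wherever they were tested, 7 kept it (C3, Ccl2, Cyp2f4, Galnt6, Hp, Il1b and Sec14l3). Another 16 lost it under those 2 alternatives only. The call was lost under others for 24: Acsl1, Acsl4, Bcl2l11, Cd1d1, Cyp3a9, Cyp51, Fcgr2b, Gadd45a, Gpx3, Ifitm3, Igfbp3, Lbp, Lman1, Mcm6, Muc4, Pdia3, Pla2g2a, S100a9, Scgb1a1, Tagln, Top2a, Vim, Xdh and Zfp423. Galnt6, Ptgs2, Cxcl2 and Cyp4b1 were tested under 18 alternatives and Serpina3n under 17, against 22 for C3. They had no present call in their dimmer group, so leaving out any array of the brighter group removed them from the test. Without normalization between arrays 90.1% of the called probe sets were higher, against 64.7% with quantile normalization.

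After Ptgs2 and Sult1c3, the genes with the largest rises included Fabp5, a fatty-acid-binding protein, which was 13.1-fold higher (log2 change 3.71 ± 0.39 SE, adjusted p = 0.0019). The secreted phospholipase gene Pla2g2a was at least 11.4-fold higher (adjusted p = 0.043), with its LPS values spread by 1.04 (SD, log2, n = 3). Its adjusted p ran from 0.0048 to 0.27 over the alternatives and missed the threshold under several, median centring (0.051) and no filter (0.27) among them. Cxcl13, a chemokine for B cells, was 8.12-fold higher (3.02 ± 0.33 SE, adjusted p = 0.0023). Galnt6, an enzyme that starts mucin-type O-glycosylation, was at least 7.87-fold higher, and the chemokine gene Cxcl2 and the serine protease inhibitor gene Serpina3n were at least 7.71-fold and 7.67-fold higher. The largest falls after Cyp4b1 were those of Cyp2a3 (13.5-fold, log2 change -3.75 ± 0.56 SE) and Cyp2f4 (8.21-fold, -3.04 ± 0.26 SE), both cytochromes P450. The peptide transporter gene Slc15a2 was 6.01-fold lower, Sec14l3 5.91-fold, Cyp3a9 5.82-fold, the zinc-finger gene Zfp423 5.08-fold and Omd 4.44-fold, with adjusted p from 0.0013 to 0.018. With a pseudocount of 64 the log2 changes of Cyp3a9, Zfp423 and Omd were -1.99, -1.72 and -1.71, against -2.54, -2.34 and -2.15 without it. In the dimmer group Lbp, Lman1, Asns and Cyp3a9 were called present on 1 of 3 arrays, and Bcl2l11, Cd14, Cyp2a3, Gpx3, Igfbp3, Muc4, Omd, Xdh and Zfp423 on 2 of 3.

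**Figure D1:**
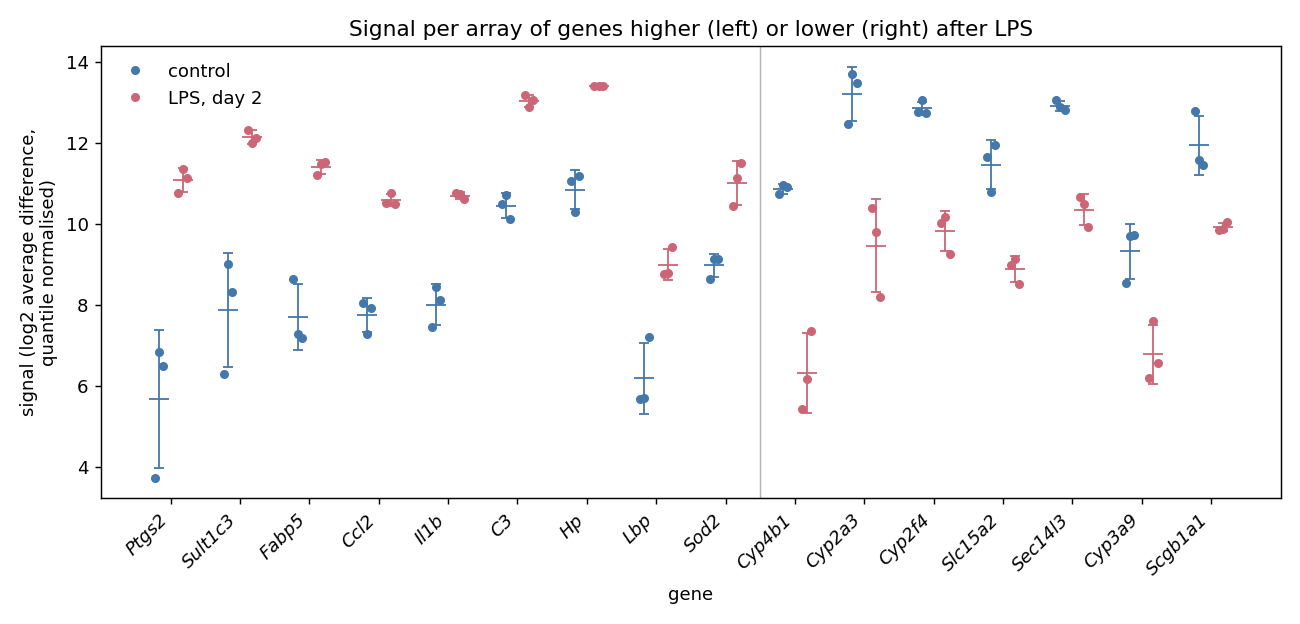
Signal of 16 genes on each array as log2 average difference after quantile normalisation, with control arrays in blue and LPS arrays in red; points are arrays, and bars give the mean and SD of 3 arrays. The 9 genes on the left were higher on all 3 LPS arrays than on any control array, and the 7 on the right were lower.

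Of 11 measured cytokine and chemokine genes, 4 rose and none fell, and 5 passed when adjusted over the list alone. Ccl2, which attracts monocytes, was 7.18-fold higher (log2 change 2.84 ± 0.27 SE, adjusted p = 0.0013), Il1b 6.51-fold higher (2.70 ± 0.28 SE) and Ccl20 4.50-fold higher (2.17 ± 0.52 SE). The list as a whole was shifted upward by camera (adjusted p = 0.00744), with a median log2 change of 1.05, or 0.88 with bounded genes at their bound. For this list adjusted p = 0.207 with an estimated correlation. Of 17 genes of NF-kB and Toll-like receptor signalling, 5 rose and 6 passed when adjusted over the list alone. Lbp, which carries LPS to its receptor, was called present on 1 of 3 control arrays and was 6.96-fold higher (2.80 ± 0.48 SE, or 2.02 with a pseudocount of 64), the mitochondrial superoxide dismutase gene Sod2 4.15-fold (2.05 ± 0.30 SE) and the LPS co-receptor gene Cd14 3.60-fold (1.85 ± 0.22 SE), while another probe set of Cd14 gave -0.31 ± 0.26 SE. The list shift had adjusted p = 0.00282, and adjusted p = 0.0844 with an estimated correlation. On the same arrays the macrophage marker list was also shifted upward (adjusted p = 0.00396, and adjusted p = 0.0889 with an estimated correlation).

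Of 13 measured antimicrobial and acute-phase genes, 8 rose and none fell, and 9 passed when adjusted over the list alone. The complement component C3 was 6.04-fold higher (log2 change 2.59 ± 0.20 SE, adjusted p = 0.0013), haptoglobin, Hp, 5.90-fold (2.56 ± 0.24 SE) and ceruloplasmin, Cp, 4.92-fold (2.30 ± 0.25 SE). S100a9, a calcium-binding protein abundant in neutrophils, was at least 4.93-fold higher. The list's upward shift had adjusted p = 2.1e-05 and a median of 1.94, or 1.21 with bounded genes at their bound. Of 9 interferon-response genes, 2 rose, Xdh (4.49-fold, adjusted p from 0.0069 to 0.17 over the alternatives) and Ifitm3 (1.83-fold, 0.018 to 0.15). The log2 change of Xdh was 2.17, or 1.46 with a pseudocount of 64. When adjusted over the list alone 2 passed, and the list did not pass (adjusted p = 0.106). Of 12 antigen-presentation genes, Cd1d1 rose (2.62-fold, 1.39 ± 0.22 SE), 4 higher and 1 lower passed when adjusted over the list alone, and the list had adjusted p = 0.245.

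Of 24 genes of the unfolded protein response and secretory pathway, 7 rose and none fell, and 12 higher and 1 lower passed when adjusted over the list alone. Lman1, a cargo receptor of the endoplasmic reticulum, was called present on 1 of 3 control arrays and was 5.44-fold higher (log2 change 2.44 ± 0.43 SE, or 1.66 with a pseudocount of 64, adjusted p = 0.014). The protein disulfide isomerase gene Pdia3 was 4.65-fold higher (2.22 ± 0.38 SE, adjusted p = 0.013), and the asparagine synthetase gene Asns 2.37-fold (1.24 ± 0.20 SE, adjusted p = 0.011). The list shift had adjusted p = 7.3e-06. With an estimated correlation, 3 process lists held their call: this one, the acute-phase list and the club-cell list, each with adjusted p = 0.0477.

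Of 16 club-cell secretory genes, 8 fell and 1 rose, and 9 lower and 1 higher passed when adjusted over the list alone. Besides Cyp4b1, Cyp2a3, Cyp2f4, Sec14l3 and Scgb1a1, the fallen genes were Aldh1a1 (3.92-fold), Ces1d (3.07-fold) and Cyp2b2 (2.95-fold). The gene that rose was Hp, which is also an acute-phase gene. The list had a median log2 change of -1.19 and adjusted p = 2.88e-05. Of 29 genes of xenobiotic metabolism, 10 fell and 1, the arylamine acetyltransferase gene Nat1, rose, and 12 lower and 2 higher passed when adjusted over the list alone. The epoxide hydrolase gene Ephx1 was 3.45-fold lower and the glutathione transferase gene Gsta1 2.50-fold lower. The list had a median of -0.58 and adjusted p = 5.82e-05, and adjusted p = 0.0844 with an estimated correlation. It shares 11 members with the club-cell list, so the 2 results are not independent.

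**Figure D2:**
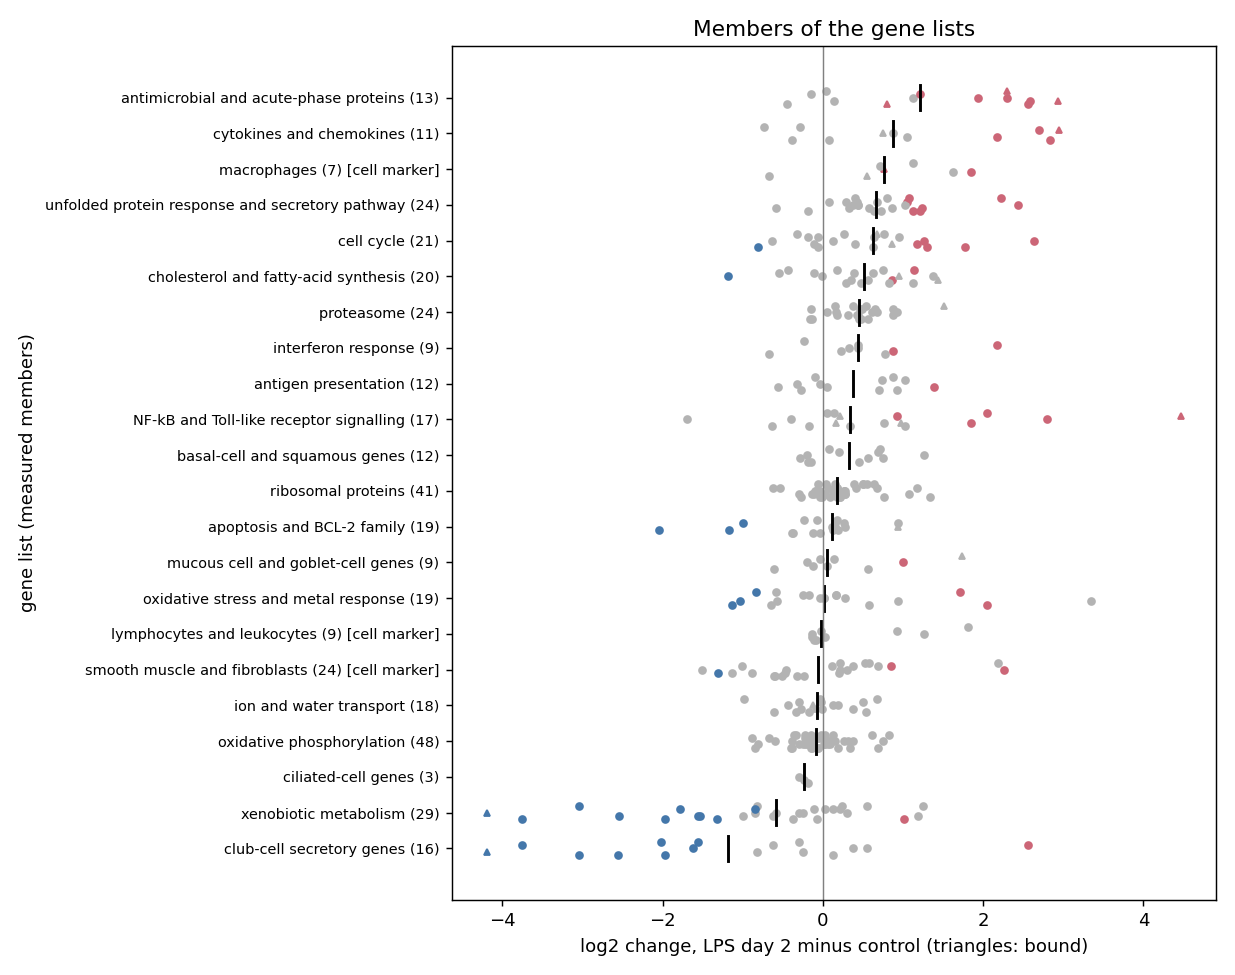
Log2 change (LPS day 2 minus control) of each measured member of the 19 process lists and the 3 marker lists large enough to test, with red for genes called higher, blue for genes called lower, grey for the rest, triangles for bounds and a black line for the list's median. The club-cell median lies at -1.19 and the acute-phase median at 1.21 with bounded genes at their bound.

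Other epithelial lists held few called genes. Of 9 mucous-cell genes, the membrane mucin Muc4 rose (1.99-fold, log2 change 1.00 ± 0.22 SE, adjusted p = 0.035, and 0.026 to 0.13 over the alternatives), 1 passed when adjusted over the list alone, and the list had adjusted p = 0.648. Muc5ac, the main secreted mucin of goblet cells, was not tested because it was called present on too few arrays. For 1 of its probe sets the average difference was -73.7, -32.3 and -60.9 on the control arrays and 404.7, 112 and 439.9 on the LPS arrays, with no present call. Another of its probe sets gave -16.6, -224.7 and -27.7 on the control arrays and -38.3, -77.3 and 15.7 on the LPS arrays. The 3 measured ciliated-cell genes gave log2 changes of -0.18 ± 0.35 SE for Foxj1, the transcription factor of ciliated cells, -0.23 ± 0.25 SE for Rsph1 and -0.30 ± 0.28 SE for Spa17, none of which passed; all 3 were above 0 without normalization between arrays. None of 12 basal-cell and squamous genes passed, over all genes or adjusted over the list alone (list adjusted p = 0.327), and Anxa1 and Itgb1 gave -0.18 ± 0.17 SE and 0.07 ± 0.15 SE. None of 18 ion and water transport genes passed by either adjustment (list adjusted p = 0.327), and Atp1b3 gave 0.67 ± 0.19 SE (adjusted p = 0.075).

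Of 21 cell-cycle genes, 5 rose and 1 fell, and 7 higher and 1 lower passed when adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, was 6.23-fold higher (log2 change 2.64 ± 0.41 SE, or 1.91 with a pseudocount of 64, adjusted p = 0.0092). The replication gene Mcm6 was 3.40-fold (1.77 ± 0.30 SE) and Top2a 2.45-fold higher (1.30 ± 0.31 SE), and Aurkb was 1.76-fold lower. The list had adjusted p = 0.0306, and adjusted p = 0.218 with an estimated correlation. Of 19 genes of apoptosis and the BCL-2 family, 3 fell: Igfbp3 (4.14-fold), Gadd45a (2.26-fold) and Bcl2l11, a pro-apoptotic member (2.00-fold). Without normalization between arrays Gadd45a and Bcl2l11 gave -0.72 and -0.64 and did not pass, with no filter none of the 3 passed, and each lost its call under other alternatives too. With adjustment over the list alone, 3 lower and 1 higher passed; the list did not pass (adjusted p = 0.343), and its median of 0.11 and mean of -0.11 differ in sign. Igf1, called present on none of the control arrays, did not pass (adjusted p = 0.062), and Bcl2 was not tested because none of its probe sets was called present on 3 arrays.

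Of 19 genes of oxidative stress and metal response, Sod2 and Gpx2 (3.26-fold) rose and Gpx3 (2.19-fold), Cat (2.05-fold) and Sod1 (1.79-fold) fell. Adjusted over the list alone, 4 higher and 5 lower passed. The list did not pass (adjusted p = 0.691), the sign of its shift turned without normalization between arrays, and Gpx3 did not pass there. Of 20 genes of cholesterol and fatty-acid synthesis, Acsl4 (2.20-fold, adjusted p from 0.013 to 0.12 over the alternatives) and Cyp51 (1.81-fold, 0.035 to 0.17) rose and Acsl1 (2.29-fold, 0.012 to 0.29) fell, while another probe set of Acsl1 gave 0.20 ± 0.30 SE; 6 higher and 1 lower passed when adjusted over the list alone. The list had adjusted p = 0.0231, and adjusted p = 0.218 with an estimated correlation. None of 24 proteasome genes passed by either adjustment, while 21 of them were above 0 and the list was shifted upward (median 0.45, adjusted p = 0.00213, and adjusted p = 0.207 with an estimated correlation). None of 48 oxidative phosphorylation genes (list adjusted p = 0.222) and none of 41 ribosomal protein genes (list adjusted p = 0.142) passed by either adjustment.

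Markers of cells other than airway epithelium were measured on the same arrays. Of 7 macrophage markers, Cd14 and Fcgr2b rose (3.60-fold and at least 1.69-fold), the latter not past the threshold without normalization between arrays, and 5 passed when adjusted over the list alone. The list had a median log2 change of 1.62, or 0.76 with bounded genes at their bound, with adjusted p = 0.00396 over the 3 tested marker lists, and adjusted p = 0.0889 with an estimated correlation. Lyz2, also a macrophage marker, had 12.89 on control and 14.01 on LPS arrays (log2, adjusted p = 0.097). None of 9 lymphocyte and leukocyte markers passed over all genes and 1 passed when adjusted over the list alone (list adjusted p = 0.547, median -0.02 and mean 0.39). Of 2 measured neutrophil markers, S100a9 rose, and Il1r2 gave 0.27 ± 0.26 SE; S100a8 was not tested because it was called present on 1 array, with -16.5, -2.5 and -28.3 on the control arrays and 155.3, 89.3 and 142.2 on the LPS arrays (average difference).

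Of 24 smooth-muscle and fibroblast markers, Fn1, fibronectin, rose 4.79-fold (2.26 ± 0.37 SE), Vim rose 1.80-fold (adjusted p from 0.022 to 0.12 over the alternatives) and the smooth-muscle gene Tagln fell 2.48-fold (-1.31 ± 0.29 SE, adjusted p from 0.012 to 0.21 over the alternatives); 2 higher and 2 lower passed when adjusted over the list alone (list adjusted p = 0.547). Among 4 alveolar type 2 markers none passed, with 0.19 ± 0.24 SE for Sftpa1, 0.08 ± 0.22 SE for Sftpd, which turned below 0 with cyclic loess, and -1.33 ± 0.76 SE for Sftpc. The lists of alveolar type 1 cells, endothelium, erythrocytes, mast cells and neuroendocrine cells had 1, 4, 2, 3 and 2 measured members, none past the threshold over all genes; 1 neuroendocrine marker passed when adjusted over the list alone. The 5S rRNA control probe set was called present on all control arrays (335 ± 49.7, SD, n = 3) and absent on all LPS arrays (119 ± 42.4), exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows. The ratio of 3' to 5' signal of Gapdh was 2.12 ± 0.987 on control and 4.12 ± 0.724 on LPS arrays (SD, n = 3, exact permutation p = 0.1). For beta-actin the ratio of 3' to middle signal was 4.02 in both groups, which is not the same measure. The 5' signal of beta-actin was 140.7, 54.5 and 120.1 on control and 116.4, 84.7 and 72.6 on LPS arrays. Its 3' signal was 1392.8, 1274.6 and 1822.1 on control and 2053.8, 2304.5 and 1896.3 on LPS arrays. Its ratio of 3' to 5' signal was not tested.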

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

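The screen of untested probe sets and the uses made here of each test to weigh an explanation were chosen after the main results were seen; the macrophage list, the estimated correlation and the normalization alternatives were themselves planned. Among 365 probe sets of list genes that were left out of the test for too few present calls, 6 had an average difference above the array's detection level on all LPS arrays and below it on all control arrays, and 3 showed the opposite. Their mean average difference on the LPS arrays was 317.1 for the eosinophil chemokine gene Ccl11, 302.3 for RT1-A3, 265.6 for Ccl3, 210.7 for the antimicrobial lipocalin gene Lcn2, 204.4 for the water channel gene Aqp4 and 129.2 for the mitotic kinesin gene Kif11. In the same order the means on the control arrays were 17.3, 21.1, -92.1, -12.5, 72.7 and 39.2. Present calls were few: none for RT1-A3 and Kif11, 1 array each for Ccl11 and Ccl3, and 2 arrays each for Lcn2 and Aqp4.

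The club-cell genes were lower after LPS, with a list median of -1.19. If RNA of other cells had diluted epithelial RNA, other epithelial genes should have fallen alike. The 24 genes of the ciliated, basal and mucous lists had a median of 0.06 (bootstrap interval -0.18 to 0.56). Lgals3 and Cd44 among them are also macrophage or leukocyte markers, so the set is not of epithelium alone and its median does not decide. The ciliated-cell genes Foxj1, Rsph1 and Spa17 gave -0.18, -0.23 and -0.30, smaller falls than the club-cell median. Of the 8 fallen club-cell genes, 6 stayed called lower without normalization between arrays and 8 with median centring or cyclic loess, which argues against scaling as the whole cause. The RNA quality signs that differed between the groups were not tested as a cause. They stay open beside dilution and a response or a loss of club cells after LPS or instillation.

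Of the cytokine, NF-kB and acute-phase genes, 4 of 11, 5 of 17 and 8 of 13 were called higher after LPS. By camera with an estimated correlation the cytokine and NF-kB lists did not pass (adjusted p = 0.207 and 0.0844). RNA of macrophages in the captured tissue is a candidate source for the cytokine and NF-kB genes: the macrophage list rose with adjusted p = 0.00396, though with adjusted p = 0.0889 with an estimated correlation. Its brightest marker, Lyz2, had a log2 signal of 12.89 on control and 14.01 on LPS arrays. Cd14 is in both the macrophage and the NF-kB list, and airway epithelium also makes lysozyme. For the acute-phase genes, the LPS array with the lowest leukocyte markers (-0.14 against the other LPS arrays) had an acute-phase median of -0.15 against them, and the LPS arrays differ too little for a test. Macrophage RNA and an epithelial response therefore cannot be told apart for the acute-phase genes. Some fibroblast and muscle markers were also bright on control arrays, with means of 13.59 for Col1a1, 12.96 for Dcn and 12.94 for Acta2 (log2). RNA of those cells was not tested as a source of the cytokine, NF-kB or acute-phase genes.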

How the results depend on the processing

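Tests with a floor of 20 or 100 or without probe sets at or below 0 were chosen after the data were seen; the other alternatives were planned. All of the 241 calls kept their direction wherever they were tested. Of results not called, 20 named genes and the oxidative-stress and smooth-muscle lists changed sign under at least 1 alternative, Foxj1, Rsph1 and Anxa1 without normalization among them. The acute-phase, club-cell and secretory lists kept their calls under every alternative run. Without normalization between arrays the median log2 change of all tested probe sets was 0.37, against 0.02, so changes there are relative to that shift: 233 were called, 90.1% of them higher against 64.7%, with 23 lower, and the ribosomal list had adjusted p = 0.023. With no filter on dim probe sets, 103 were called (76 higher, 27 lower), 59 of them among the 241, and 34 of 47 called genes followed through the alternatives lost their call, Ptgs2, Sult1c3, Scgb1a1 and Cyp2a3 among them, over more probe sets tested. With probe sets present on all arrays camera called 0 marker lists, and the NF-kB, cell-cycle and cholesterol lists each had 0.22. Without the intensity trend 48 were lower, and with an unmoderated t statistic 59 were called (46 higher, 13 lower) and 37 of the 47 lost their call. With an estimated correlation 3 process lists and 0 marker lists passed, with adjusted p of 0.21 for cytokines, 0.084 for NF-kB and for xenobiotic metabolism, 0.22 for cell cycle and for cholesterol, 0.21 for proteasome and 0.089 for macrophages. The cause of these differences between alternatives was not tested.

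Leaving out each array in turn gave 78 to 230 called probe sets, 48 to 160 higher and 30 to 70 lower, and between 8 of 46 and 20 of 40 of the followed genes still tested lost their call: 137, 78 and 98 called without LPS replicate 1, 2 and 3, and 55 and 54 lower without control replicate 2 and 3. Process lists called ranged from 5, without LPS replicate 2, to 10, without LPS replicate 1, and marker lists from 0, without LPS replicate 1, to 1. Adjusted p ranged from 0.0016 to 0.1 for cytokines, 0.0023 to 0.053 for NF-kB, 0.045 to 0.17 for interferon response, 0.033 to 0.58 for antigen presentation, 0.024 to 0.1 for cell cycle, 0.015 to 0.14 for cholesterol, 0.01 to 0.94 for ribosomal proteins and 0.0023 to 0.068 for macrophages. The call was lost for cytokines (0.1) and NF-kB (0.053) without LPS replicate 2 and for macrophages (0.068) without LPS replicate 1. It was lost for cell cycle without control replicate 1 (0.07), LPS replicate 2 (0.058) or 3 (0.1), and for cholesterol without control replicate 1 (0.067) or 3 (0.073) or LPS replicate 2 (0.14) or 3 (0.098). Without control replicate 1 the ribosomal list passed (0.01), without LPS replicate 1 interferon response (0.045) and without LPS replicate 3 antigen presentation (0.033).

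Whether replicate numbers pair the samples could not be told from so few arrays. With each group's mean subtracted per probe set, the deviations of same-numbered arrays correlated at 0.079, 0.18 and -0.069. By these deviations control replicates 1 and 2 correlated best with their own number, and control replicate 3 did not. With the replicate block 202 were called (130 higher, 72 lower), of which 185 were shared. No scan batch was found in the files, so that alternative was not run, and the value table equals the main input. For named genes the alternatives kept sign and call in 1385 cases, lost the call in 185 and gained it in 7. In 48 cases the sign of a gene not called changed. These counts do not measure how far the log2 changes shifted.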

Other observations

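Outside the fixed lists, 104 genes passed the threshold, 71 higher and 33 lower after LPS; the genes named here, and the tests of gene families and of array splits below, were chosen after the main results were seen. Timp1, an inhibitor of matrix metalloproteinases, was at least 6.79-fold higher, and the immediate-early gene Egr2 was 6.79-fold higher (log2 change 2.76 ± 0.35 SE, limma adjusted p = 0.0049). The iron transporter gene Slc11a2 was 3.95-fold higher (1.98 ± 0.20 SE), the arginine transporter gene Slc7a1 also 3.95-fold (1.98 ± 0.29 SE, called present on 1 of 3 control arrays) and Gch1, of tetrahydrobiopterin synthesis, 3.72-fold (1.89 ± 0.45 SE). Serp1 was 3.74-fold higher (1.90 ± 0.25 SE), Erp29 2.80-fold (1.49 ± 0.24 SE) and Lrrc59 2.48-fold (1.31 ± 0.20 SE).

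Among the falls, the retinol carrier gene Rbp4 was 3.73-fold lower (-1.90 ± 0.23 SE, adjusted p = 0.0041), the retinoic acid receptor gene Rara 1.95-fold lower (-0.97 ± 0.17 SE, called present on 2 of 3 control and 1 of 3 LPS arrays), and Aldh1a1, which makes retinoic acid, is named with the club-cell genes. The peptide-processing genes Pam and Cpe were each 2.25-fold lower, with -1.17 ± 0.18 SE for both. No test of these as groups was run.

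Each of 3 gene families was then tested with camera because called members had been seen, so these tests are not independent of what prompted them. Complement genes (9 measured, 5 higher and 1 lower) had adjusted p = 0.0035 and heat-shock genes outside the secretory list (14 measured, 3 lower) 0.0039. The aminoacyl-tRNA synthetase genes Kars1 and Tars1 with Aimp2, a complex member that is not a synthetase, had 0.028 (3 measured, Tars1 and Aimp2 higher). That family is below the minimum of 5 measured members set for the lists. Hspb1, among the lower heat-shock genes, gave -0.79 with its brightest probe set. Its other tested probe sets gave -0.02 ± 0.36 SE and -0.06 ± 0.24 SE, and that of Dnajb1 gave -0.78 ± 0.42 SE, none called. With an estimated correlation all 3 families had adjusted p = 0.12. The members not called had medians of 0.11, -0.13 and 0.10, so whether each family moved as a whole stays open.

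The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 241 probe sets with limma and the highest other split 0, and 1 of the 10 splits, the real one, reached 241. Other splits gave 35 to 128 probe sets at an unadjusted p under 0.05, below the 151 expected by chance. Each of them has LPS arrays in both groups, so an LPS difference widens the spread within groups, and their 0 does not measure calls by chance. For process lists the real split called 9 and the highest other 6, and 1 of the 10 splits reached 9. For marker lists the real split called 1 and the highest other 2, and 5 of the 10 splits reached 1.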
